A study of Drosophila melanogaster with 3 samples.

How the data were processed

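Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex collected 0 to 18 h after egg laying, from a transgenic line that carries CG12219 with green fluorescent protein (GFP) at its C-terminus. The labels give 3 biological replicates of this 1 group. Chromatin was fragmented by sonication, with a size range of 200 to 800 bp. The labels disagree on one point: a free-text line calls each sample an input control, while the assay title, the antibody field, a control named as a separate experiment and the deposited peak lists describe immunoprecipitated samples. The samples are treated here as immunoprecipitations. No untagged or mock immunoprecipitation was used here.

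Each replicate came with 1 peak list, and 2 further lists, a pooled list and the list of peaks passing the irreproducible discovery rate (IDR) step, belong to the whole series. Per the file listing deposited with the samples, the replicate lists were called on each replicate's alignments against a control alignment, and the pooled list on the alignments of all 3 replicates. These 4 lists hold peaks together with background calls meant as input for IDR, so a call among the 30000 of each list is not by itself taken as a binding site. Coordinates are in the dm6 build, per the labels. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, deposited without a stated normalization, so it was used only to rank peaks within a list. The deposited −log10 q value of each peak is the authors' as well, and it reached its maximum in 3872 of the 4187 IDR peaks, so it was used only to break ties in signal. The offset of the summit within each interval is also as the authors deposited it. All 4187 IDR peaks were found in the pooled list with equal values, and they are its 4187 highest-signal calls. The sequencing depth of each library is unknown, since the files hold no read counts, and no interval below covers sequencing depth. The intervals given for shares of peaks or genes are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only.

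Annotation came from Ensembl release 115 (BDGP 6.54) and sequence from the RefSeq genome. The 7 chromosomes 2L, 2R, 3L, 3R, 4, X and Y were used, whose lengths in the sequence used are those of dm6, and no peak or gene lay beyond a chromosome's end. Transposable elements in the annotation were left out, which left 18277 genes, 13968 of them protein-coding, with 35612 transcripts and 23694 distinct transcription start sites (TSS). All computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

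A summit counted as at a TSS when it lay within 500 bp of one. The share at a TSS was tested against 1000 random placements of the summits on the same chromosome, two-sided, and the smallest p these placements can give is 0.002. Each summit received 1 annotation class, in the order TSS within 500 bp, 5' UTR, coding exon, 3' UTR, noncoding exon, intron, intergenic. Replicates were compared through their 4187 highest-signal calls, the number of IDR peaks. A call counted as shared when its summit lay within 250 bp of one of the other replicate's, and chance was taken from 100 circular shifts along each chromosome. In a comparison chosen after the data were seen, calls were drawn so that every replicate held the same number in each bin of 5 points of A+T, with a bootstrap over blocks of 1000000 bp (1000 draws). Peaks per chromosome were tested with exact binomial tests. Gene lists were tested with Fisher's exact test, two-sided, as the share of genes with an IDR summit within 500 bp of any of their TSS, against all other protein-coding genes, or against all other genes for lists of RNA genes. Within genes of equal TSS class a Mantel-Haenszel test and difference were used. There were 31 lists, 10 of whose symbols matched by an older symbol and 8 of whose symbols found no match. Sequence was searched for 23 consensus motifs within 100 bp of the summit, against flanks centred 500 bp away (exact McNemar test) and against windows at the same offset from a random draw of protein-coding TSS over 1000 bp from any IDR summit (Fisher's exact test). For 6-mers and 8-mers within 50 bp of the summit, alternate peaks in genome order ranked the k-mers and the remaining 2093 peaks tested the top 10. Flank shares given for motifs and k-mers are the mean of both sides, while each McNemar test used 1 side per peak, drawn at random. P-values were adjusted by the Benjamini-Hochberg method over the arms, classes, lists, motifs or k-mers of each family, with 0.05 as the threshold. Peaks are not independent samples of embryos, so these p-values describe 1 set of peaks and not the spread between replicates.

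Genes named in the text follow a rule set before the data were examined, as were the lists, the motifs and the tests other than those said in the text to have been chosen after the data were seen. Named are the genes nearest to the 20 IDR peaks with the highest signal, up to 4 members with the highest-signal peak for each list past the threshold and for the Hox, gap, pair-rule and insulator lists, and CG12219 with its neighbours. The exceptions are the genes of the closing section, the ribosomal protein genes that share a summit with a named gene, and ush, whose intron holds a named summit. These were chosen after the values were seen. Alternatives tried were each replicate left out (with the summits shared by the top calls of the remaining pair as the peak set), the IDR peaks above the median signal, the top calls shared by all 3 replicates, other windows and distances, other gene assignments, other backgrounds and other splits. Without replicate 1 the shared summits were those of replicate 2, and in the other shared sets those of replicate 1. The sets without replicates 1, 2 and 3 held 3137, 2957 and 2842 summits. A call lost with a replicate left out can thus also reflect the smaller set or the source of the summits.

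The code was tested on simulated data. Planted gene lists were found in 20 of 20 draws, and 1 of 600 random lists passed the threshold. A planted motif was found in 20 of 20 draws with 3 of 440 other motif tests past the threshold, and a planted 8-mer ranked first in 20 of 20 draws, with 0 of 200 tests past the threshold when none was planted. The motif and 8-mer draws used random sequence with equal shares of all bases at summit and flank. Their error counts thus do not cover the A+T rise of the real summits (7.69 points). Random placements passed the TSS test in 0 of 20 draws, and sets drawn by chromosome length passed the arm test in 5 of 140 tests. A planted overlap of 70.0% was measured as 70.6%.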

Results

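The series asks where the tagged protein of CG12219, a gene known by its annotation number, sits on the genome of the whole embryo between 0 and 18 h of development. The data comprise ChIP-seq peak lists for 3 biological replicates of 1 group, the embryos expressing CG12219 fused to GFP. There was no second condition, so the comparisons are between replicates, between peaks and random positions, and between groups of genes. The list deposited after the irreproducible discovery rate (IDR) step held 4187 peaks, which are the 4187 highest-signal calls of the pooled list. Their intervals merged into 4108 regions that cover 0.993% of the 7 chromosomes used. Peak widths ran from 98 to 739 bp, and 2717 peaks had the width of 390 bp. The depth of the libraries is unknown.

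The strongest peaks lay at promoters and in introns of genes of diverse function, and the replicates ranked them alike. The highest signal, 4801.61 in the authors' units, lay at -35 bp from the TSS of Ugalt, a UDP-galactose transporter gene (dm6, X, 2703702 to 2704078, negative offsets being upstream), and this peak ranked first in all 3 replicates. The peak of rank 2 (2L, 6612418 to 6612920) lay in an intron of CG11050, at 1015 bp from its TSS, and ranked 5, 2 and 3 in replicates 1, 2 and 3. The peak of rank 3 (3L, 19590440 to 19590796) lay at -93 bp from the TSS of CG14100 and ranked 3, 5 and 2. Next came px (plexus, a wing vein patterning gene) at rank 4 (2R, 22514118 to 22514498), at -202 bp and ranked 7, 4 and 8, and CenG1A at rank 5 (2L, 13835293 to 13835652), ranked 2, 6 and 6, whose promoter is shared with the mitochondrial ribosomal protein gene mRpS23. The summit of rank 6 (2L, 480884 to 481298) lay in an intron of ush, at -1397 bp from the TSS of cbt (cabut, a zinc finger transcription factor), and ranked 8, 3 and 11. CG1888 followed at rank 7 (2R, 9547013 to 9547395), ranked 4, 11 and 5, then ph-p, a Polycomb group gene, at rank 8 (X, 2137176 to 2137550), ranked 6, 12 and 4. PNPase, a mitochondrial polynucleotide phosphorylase gene, stood at rank 9 (3R, 31404487 to 31404837), ranked 9, 10 and 7. Lk6, a protein kinase gene, held the peak of rank 10 (3R, 11760875 to 11761243) in an intron, at -966 bp from its nearest TSS, ranked 10, 9 and 10.

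The peak of rank 11 (2R, 13035155 to 13035525) was the 1 intergenic peak among the first 20, at 11905 bp from the nearest TSS, that of CG13323, and ranked 11, 8 and 9. CG11309 stood at rank 12 (3L, 21304387 to 21304750, ranked 13, 7 and 14), and Chro, which encodes the chromodomain protein Chromator, at rank 13 (3L, 22878715 to 22879077, ranked 12, 13 and 12). CG9147 stood at rank 14 (2L, 6065940 to 6066277, ranked 15, 15 and 13) and the arginine methyltransferase gene Art3 at rank 15 (3R, 15229365 to 15229699, ranked 18, 16 and 15). CG18549 followed at rank 16 (3R, 12449006 to 12449349, ranked 20, 14 and 19), and an intron of CG9663 at rank 17 (2L, 3301996 to 3302575, ranked 14, 25 and 20). Next were Pal1 at rank 18 (2R, 9959718 to 9960096, ranked 23, 17 and 23), Tina-1 at rank 19 (2R, 24942374 to 24942759, ranked 36, 18 and 25) and the glycolytic gene Gapdh2 at rank 20 (X, 15867789 to 15868151, ranked 34, 19 and 31). In all, 15 of these 20 peaks had a TSS within 500 bp and 4 were intronic. The summits at CG11309, Chro, CG9147 and Pal1 also lay within 500 bp of the TSS of a further gene each. That at Art3 lay at -130 bp from the TSS of the mitochondrial ribosomal protein gene mRpS10. None of the 20 ranked lower than 36 in any replicate. The 20 were chosen by their signal in the pool of these same replicates, which by itself favours high ranks in each.

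Sequence at the strongest summits was rich in A and T. The 61 bp centred on the Ugalt summit (X, 2703857 to 2703917, upstream of the gene) read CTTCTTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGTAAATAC, 73.8% A+T. The 61 bp in the CG11050 intron (2L, 6612672 to 6612732) read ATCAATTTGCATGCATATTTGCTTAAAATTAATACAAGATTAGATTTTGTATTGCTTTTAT, 78.7% A+T. Those upstream of CG14100 (3L, 19590587 to 19590647) read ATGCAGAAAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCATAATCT, 70.5% A+T.

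Across the whole list the replicates shared most of their top calls. Of the 4187 highest-signal calls of a replicate, 70.9% ± 3.2 (SD, n = 3 pairs) had a counterpart within 250 bp in another replicate, against means of 1.52% to 1.57% after circular shifts. Replicates 2 and 3 shared most (74.4%), replicates 1 and 3 shared 70.3%, and replicates 1 and 2 shared 68.0%. Among the IDR peaks, 76.6% had a counterpart among the top calls of replicate 1, 86.7% in replicate 2 and 83.2% in replicate 3, and 2512 had one in all 3. Including calls of any rank, 4086 IDR peaks (97.6%) appeared in all 3 lists. Across the IDR peaks found in both lists, ranks correlated with Spearman's rho of 0.609 for replicates 1 and 2, 0.738 for 1 and 3 and 0.721 for 2 and 3. Peaks are not independent replicates, and these values describe a set that holds the highest-signal calls of the pooled list, to which all 3 replicates contributed. The top calls of the replicates differed in base composition. The genome sequence within 50 bp of the top 4187 summits held 61.0% A+T in replicate 1, 66.6% in replicate 2 and 63.9% in replicate 3. The composition of the sequenced libraries was not measured.

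Start sites, introns and intergenic DNA held nearly all summits, and coding exons more than 500 bp from a TSS held almost none. Of the 4187 summits, 1813 (43.3%, interval 41.8 to 44.8%) lay within 500 bp of a TSS, against 13.6% ± 0.535 (SD) of random positions (permutation by random placement, p = 0.002, the smallest the 1000 placements can give). The lowest-ranked 4187 calls lay at a TSS in 19.3%, 19.6% and 16.1% of cases in replicates 1, 2 and 3. Away from start sites, 1664 summits (39.7%) were intronic, against 39.5% of random positions (permutation, adjusted p = 0.701). Only 9 summits (0.215%, interval 0.0983 to 0.408%) fell in coding exons more than 500 bp from a TSS, against 13.7% of random positions, and 36 (0.860%) in 3' UTRs against 4.42%. Intergenic summits numbered 589 (14.1% against 27.2%). The 3 shortfalls each had an adjusted p of 0.0035. Noncoding exons held 47 summits (1.12% against 0.814%, permutation, adjusted p = 0.0476) and 5' UTRs 29 (0.693% against 0.782%, adjusted p = 0.697). Coding exons held 7.31% of the lowest-ranked pooled calls. Against random positions of equal A+T content, a setting chosen after the data were seen, coding exons were expected at 5.90%, and the intronic share then lay below expectation, 39.7% against 43.7% (permutation p = 0.002, the smallest the placements can give).

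**Figure D1:**
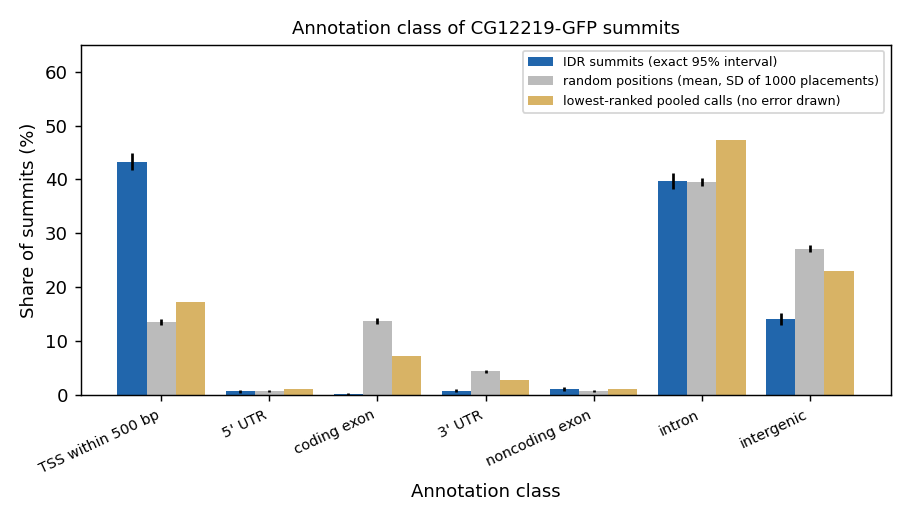
Share of summits in each annotation class (percent), for the 4187 IDR summits with exact 95% intervals, for random positions on the same chromosome with the SD of 1000 placements, and for the 4187 lowest-ranked pooled calls. The TSS class held 43.3% of IDR summits against 13.6% of random positions, and coding exons more than 500 bp from a TSS 0.215% against 13.7%.

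Summits at start sites mostly lay upstream. The median position was -109 bp relative to the nearest TSS, with quartiles at -207 and 3 bp, and 1346 of the 1813 summits (74.5% of those not exactly at the TSS, exact binomial p = 1.68e-100) were upstream. The 838 peaks with the highest signal were at a TSS in 53.1% of cases and the 837 with the lowest in 42.2%, a difference of 10.9 points (Fisher's exact test, two-sided, p = 8.39e-06). The groups of peaks between them lay at 40.9%, 38.8% and 41.6%, so the excess was in the highest-signal group.

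Peaks were found on every chromosome used except Y. Counts were 812 on 2L, 768 on 2R, 864 on 3L, 974 on 3R, 756 on X, 13 on chromosome 4, the small, largely heterochromatic autosome, and 0 on Y. Against sequence length, 2L held 1.13 times the expected number (exact binomial test, adjusted p = 3.76e-04, but 0.0519 for the 2093 peaks with the higher signal) and chromosome 4 held 0.320 times (adjusted p = 2.80e-06), while 104.2 peaks were expected on Y. Against the number of TSS positions, X held 1.10 times the expected number (exact binomial test, adjusted p = 0.0119) and 2R held 0.893 times (adjusted p = 8.71e-04). On chromosome 4 the count was 0.402 times that expected from TSS positions (exact binomial test, adjusted p = 6.60e-04), a call lost without replicate 2 (adjusted p = 0.127), for the higher-signal peaks (0.219) and for the top calls of all 3 replicates (0.116), and the absence of peaks on Y gave an adjusted p of 2.50e-08. The excess of 3L over TSS positions (1.08 times, adjusted p = 0.0245) was lost with any 1 replicate left out, where the exact binomial adjusted p was 0.431, 0.314 and 0.0793 without replicates 1, 2 and 3. Repeated sequence on Y limits what peak calling can find there.

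The cytosolic ribosomal protein genes, which encode the structural proteins of the cytoplasmic ribosome, stood furthest above other genes. A summit lay within 500 bp of the TSS of 67 of these 85 genes (78.8%, interval 68.6 to 86.9%), against 13.9% of other protein-coding genes (odds ratio 23.1, Fisher's exact test, adjusted p = 2.47e-39). Peaks lay at 40 of 48 genes for large subunit and 27 of 37 genes for small subunit proteins. The strongest were at RpS27 (3R, 25247354 to 25247677, summit at 7 bp from the TSS, rank 187, and 85, 573 and 107 in replicates 1, 2 and 3) and RpS4 (3L, 13041650 to 13041987, at 17 bp, rank 190, and 102, 311 and 163). RpL7 (2L, 10200905 to 10201179, at 48 bp) ranked 213, and 83, 537 and 151 in the replicates, and RpL31 (2R, 9587083 to 9587345, at -9 bp) ranked 278, and 160, 422 and 216. The median rank of these peaks in the IDR list was 997, 55 of the 67 lay among the 2093 highest-signal peaks, and 57 were among the top calls of all 3 replicates. Most of the 67 peaks ranked lower in replicate 2 than in replicate 1, as those at RpS27, RpS4, RpL7 and RpL31 did. Of the 18 genes with no peak, 11 had a call of lower rank in the pooled list, where 44.8% of all protein-coding genes had a call of any rank. Mitochondrial ribosomal protein genes, by contrast, carried a peak in 15 of 73 cases (20.5%, exact adjusted p = 0.312), which is 6.29 points above other genes. The difference turned to -10.5 points with each peak given to the nearest gene at any distance (exact adjusted p = 0.0410).

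**Figure D2:**
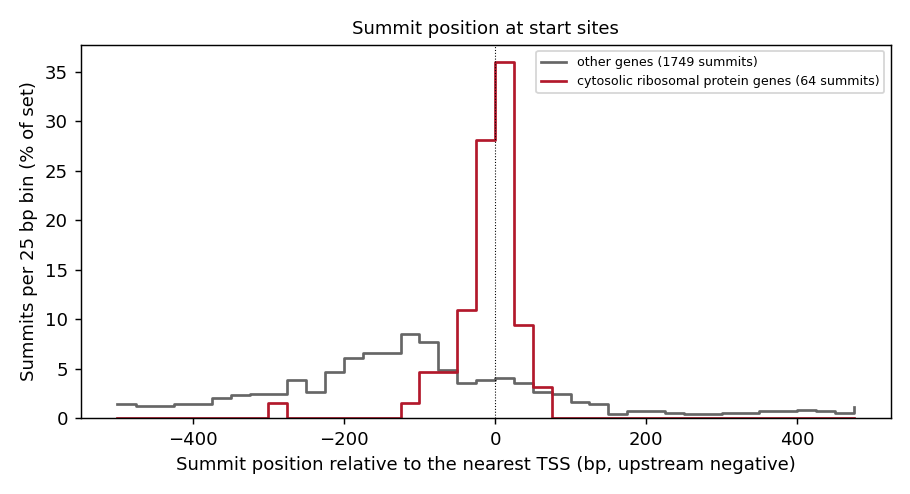
Summit position relative to the nearest TSS (bp, upstream negative) as the percent of each set per 25 bp bin, for summits nearest to a cytosolic ribosomal protein gene TSS (64 summits) and for the other promoter summits (1749). The medians are -2 bp and -116 bp.

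Genes for insulator and architectural proteins, which bind chromatin boundaries, carried peaks in 10 of 23 cases (43.5%, interval 23.2 to 65.5%) against 14.2% of other genes (odds ratio 4.63, exact adjusted p = 0.0023). The strongest were at Chro (summit at 103 bp), which ranked 13, and Cp190 (3R, 15275228 to 15275552, at -152 bp), which ranked 146 in the IDR list and 221, 112 and 205 in the replicates. Dref, which encodes the factor that binds the DNA replication-related element, ranked 516 (2L, 9967205 to 9967429, at -71 bp, and 407, 672 and 394 in the replicates), and Trl, which encodes GAGA factor, ranked 805 (3L, 14757107 to 14757295, and 1009, 1144 and 448). The summits at Chro, Cp190 and Dref each also lay within 500 bp of the TSS of a neighbouring gene, which for Dref is the ribosomal protein gene RpL13, at -13 bp from the same summit. So did most of the summits counted for the other genes of this list, so the share includes many promoters shared with a neighbour. With each peak given to the single nearest gene at any distance, which also brings in the peaks away from start sites, 6 of the 23 genes carried one and the list was no longer past the threshold (exact adjusted p = 0.32). Polycomb and trithorax group genes carried peaks in 9 of 30 cases (30%, exact adjusted p = 0.0943) and genes of the general transcription machinery in 10 of 40 (25%, exact adjusted p = 0.173).

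**Figure D3:**
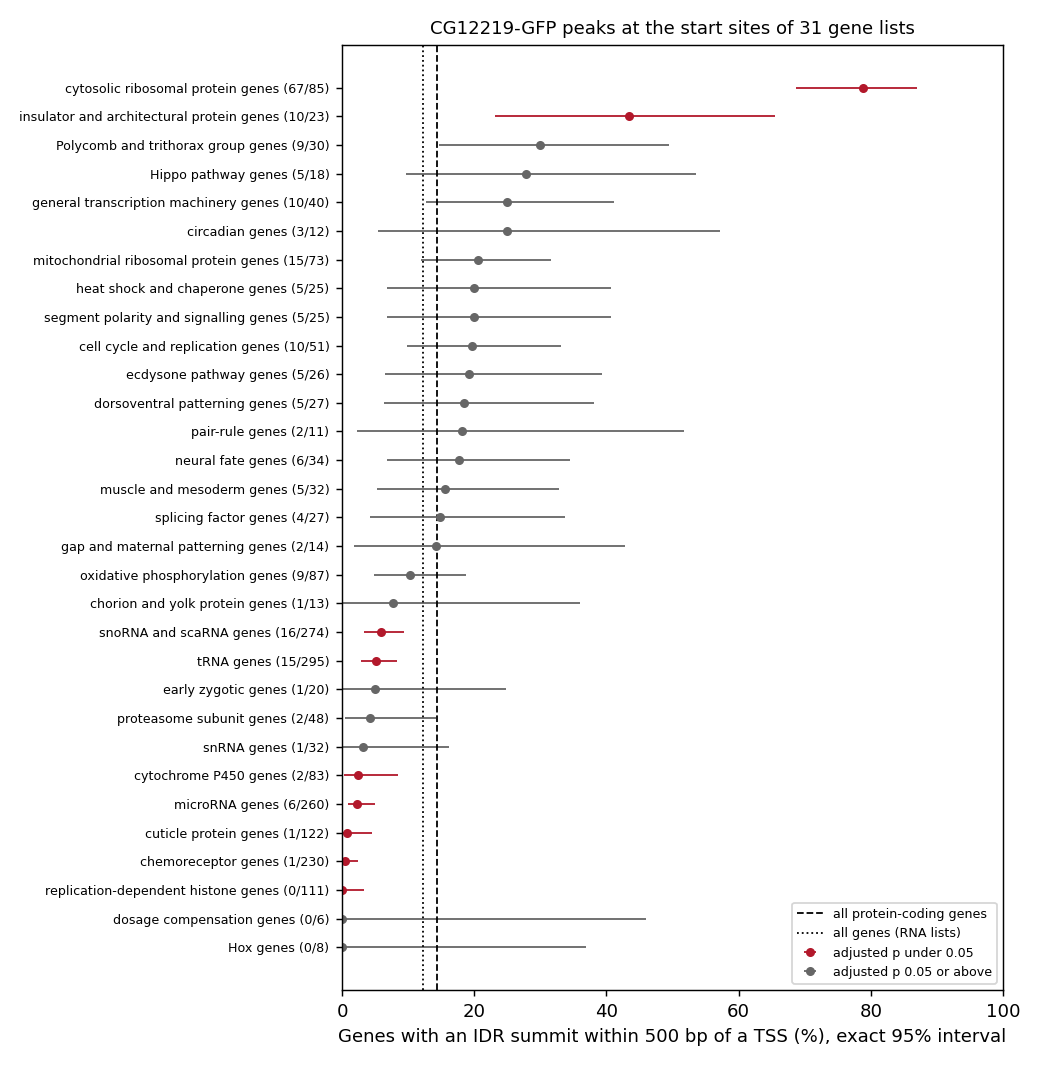
Percent of the genes of each of 31 lists with an IDR summit within 500 bp of a TSS, with exact 95% intervals, beside all protein-coding genes (14.3%) and all genes (12.2%). Cytosolic ribosomal protein genes (78.8%) stand apart, and chemoreceptor and cuticle protein genes lie near 0.

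Chemoreceptor, cuticle protein, cytochrome P450 and replication-dependent histone genes carried peaks at their start sites less often than other genes. Chemoreceptor and odorant-binding protein genes carried a peak in 1 of 230 cases (0.435%, exact adjusted p = 3.43e-13), at Obp99b (3R, 29717021 to 29717266, rank 404, and 304, 803 and 210 in the replicates). Cuticle protein genes did in 1 of 122 cases (0.820%, exact adjusted p = 1.86e-06), at Cpr65Av (3L, 6140196 to 6140585, rank 3232, and 3373, 4857 and 2404). Cytochrome P450 genes did in 2 of 83 cases (2.41%, exact adjusted p = 0.0020), at Cyp6u1 (2R, 6975019 to 6975209, rank 583, and 974, 622 and 457) and Cyp317a1 (2R, 14898813 to 14899202, rank 2120, and 3694, 1757 and 2664), and this call was lost without replicate 2 (exact adjusted p = 0.156) and without replicate 3 (exact adjusted p = 0.138). None of the 111 replication-dependent histone genes carried a peak (0%, upper bound 3.27%, exact adjusted p = 4.88e-07), and these are near-identical repeated copies at which reads cannot be placed uniquely.

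Short RNA genes carried peaks less often than all other genes, of which about 12.3% did. MicroRNA genes did in 6 of 260 cases (2.31%, exact adjusted p = 9.81e-08), led by mir-9378 (2L, 10751994 to 10752223, rank 871, and 342, 1975 and 632), mir-9377 (X, 12665525 to 12665761, rank 1035, and 904, 1010 and 1177), mir-4962 (X, 3777198 to 3777587, rank 1441, and 869, 2599 and 966) and mir-2491 (X, 22833672 to 22833815, rank 1669, and 1971, 1927 and 1556). tRNA genes did in 15 of 295 cases (5.08%, exact adjusted p = 2.43e-04), with the highest signal at tRNA:Tyr-GTA-1-8 (3R, 8669202 to 8669533, rank 59, and 40, 52 and 103), tRNA:Leu-TAA-2-1 (3R, 24112551 to 24112940, rank 1039, and 1289, 1191 and 1204), tRNA:Phe-GAA-1-2 (X, 6744164 to 6744313, rank 1105, and 474, 1776 and 922, a summit at 322 bp from the tRNA gene and at 17 bp from the TSS of the ribosomal protein gene RpL17) and tRNA:Trp-CCA-2-2 (2R, 18639079 to 18639468, rank 1413, and 1192, 1916 and 1710). Small nucleolar and Cajal body RNA genes did in 16 of 274 cases (5.84%, exact adjusted p = 0.0021), led by snoRNA:Or-aca5 and snoRNA:Psi28S-2949 at a common summit (2R, 9095086 to 9095334, rank 319, and 190, 588 and 200), snoRNA:U49:66Da (3L, 8600867 to 8601130, rank 320, and 191, 641 and 162) and snoRNA:Or-CD11a (3L, 3222882 to 3223099, rank 544, and 430, 919 and 371). The last 2 are summits of ribosomal protein genes, at 3 bp from the TSS of RpL14 and at -22 bp from that of RpL28, while they lie at -464 and -441 bp from the small nucleolar RNA genes. Each summit named here for a microRNA, tRNA or small nucleolar RNA gene also lay within 500 bp of the TSS of at least 1 further gene. In all, 8 of the 16 small nucleolar RNA genes with a peak shared their summit with a ribosomal protein gene. A start site is here the annotated 5' end of a transcript, and whether transcription of these RNA genes begins there was not tested. Such genes have few annotated start sites. Within genes of equal TSS class (1 or more than 1) the tRNA and small nucleolar RNA differences shrank to -3.43 and -2.73 points. Both were then no longer past the threshold in a Mantel-Haenszel test. The small nucleolar RNA call was also lost without replicate 1 (exact adjusted p = 0.159) and without replicate 2 (exact adjusted p = 0.0951), and with a window of 1000 bp the difference turned to 1.66 points above other genes.

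No difference from other genes was detected at the start sites of the classical patterning genes. None of the 8 Hox genes carried a peak there (interval 0 to 36.9%, exact adjusted p = 0.740), which with 8 genes leaves a wide range open. Among gap and maternal patterning genes 2 of 14 did (exact adjusted p = 1), cnc at rank 813 (3R, 23189965 to 23190158, and 923, 774 and 887) and bcd at rank 3696 (3R, 6759468 to 6759857, and 2231, 6451 and 2106). Among pair-rule genes 2 of 11 did (exact adjusted p = 0.762), the hairy gene, annotated as hry, at rank 3746 (3L, 8675575 to 8675964, and 1677, 5490 and 2758) and sob at rank 3827 (2L, 3580706 to 3581095, and 6257, 3337 and 4354). Shares in the other lists, none past the threshold with the IDR peaks and a window of 500 bp, were 5 of 25 segment polarity and signalling genes, 5 of 27 dorsoventral patterning genes, 6 of 34 neural fate genes, 5 of 32 muscle and mesoderm genes, 1 of 20 early zygotic genes, 5 of 26 ecdysone pathway genes and 5 of 25 heat shock and chaperone genes. Further shares were 10 of 51 cell cycle and replication genes, 4 of 27 splicing factor genes, 0 of 6 protein-coding dosage compensation genes, 5 of 18 Hippo pathway genes, 3 of 12 circadian genes, 9 of 87 oxidative phosphorylation genes, 2 of 48 proteasome subunit genes, 1 of 32 snRNA genes and 1 of 13 genes taken as chorion and yolk protein genes by their symbols. The Hippo pathway genes came past the threshold without replicate 3 (23.1 points above other genes, exact adjusted p = 0.0281). With a window of 1000 bp the heat shock and chaperone genes did (22.7 points, exact adjusted p = 0.0216), as did the proteasome subunit genes (-13.2 points, exact adjusted p = 0.0366). The 1 chorion and yolk gene is Cp190, the insulator protein gene, which the symbol rule took in by its first letters and which encodes no chorion protein. With each peak given to its nearest gene at any distance, 7 lists lay above other genes, among them segment polarity and signalling genes by 38.8 points and muscle and mesoderm genes by 26.5 points. That setting changes both the distance and the number of genes per peak and does not allow for the length of DNA around each gene. Against random positions, peaks away from start sites were more frequent at segment polarity and signalling genes (29 against 10.3, permutation adjusted p = 0.0155) and at muscle and mesoderm genes (24 against 11.7, permutation adjusted p = 0.0413). They were not past the threshold for Hox, gap, pair-rule, dorsoventral and ecdysone pathway genes.

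Summit sequence was richer in A and T than its surroundings. Sequence within 50 bp of the summit held 64.9% A+T on average, against 57.2% in the flanks 500 bp away, a rise of 7.69 points (95% interval over summits 7.31 to 8.08). The rise was 7.88 points at start sites and 7.55 points elsewhere. It was 11.0 points over the 500 peaks with the highest signal, and it differed between replicates, at 2.99, 9.42 and 6.40 points over the top calls of replicates 1, 2 and 3. At the 64 summits nearest to a ribosomal protein gene TSS no rise was measured (-2.04 points, interval -4.37 to 0.286).

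**Figure D4:**
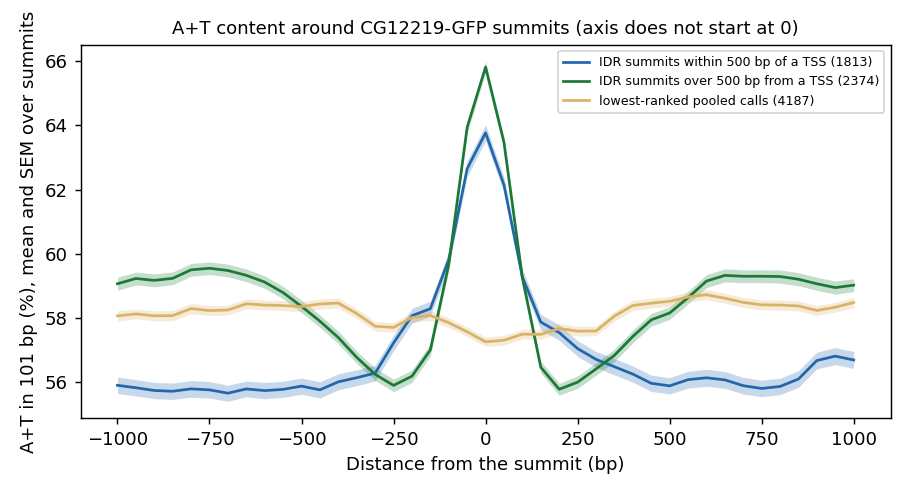
Mean A+T content (percent, in windows of 50 bp on either side, shaded SEM over summits) against distance from the summit, for 1813 IDR summits within 500 bp of a TSS, 2374 IDR summits elsewhere and the 4187 lowest-ranked pooled calls. Both sets of IDR summits peak at the centre (63.8% and 65.8%), and the lowest-ranked calls have no such peak.

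Of 23 consensus motifs, 11 were more frequent within 100 bp of the summit than in the flanks and 2 were less frequent. The largest difference was for WGATAR, the site of GATA factors, present at 39.6% of summits against 29.8% of flanks (exact McNemar test, adjusted p = 5.20e-24). It was followed by the homeodomain site TAATTA (15.9% against 11.9%, exact adjusted p = 9.18e-08), lost without replicate 2 (exact adjusted p = 0.250), the TATA box consensus (11.5% against 7.97%, exact adjusted p = 1.36e-05) and CGATA, the site of BEAF-32 (25.1% against 21.7%, exact adjusted p = 0.0019), lost without replicate 1 (exact adjusted p = 0.0947). Ohler motif 7 (CAKCNCTR), a core promoter element, was at 9.10% against 6.21% (exact adjusted p = 7.86e-07). Rarer sites were the DNA replication-related element (1.67% against 0.609%, exact adjusted p = 2.90e-04), the CTCF core (1.41% against 0.597%, exact adjusted p = 4.44e-04) and the Su(Hw) core (1.10% against 0.322%, exact adjusted p = 2.90e-04), the last lost without replicate 2 (exact adjusted p = 0.125). The GATA, homeodomain and TATA sites are themselves rich in A and T. Against start sites without a peak, several of these motifs were not past the threshold at summits near a TSS. These were WGATAR (35.9% against 33.1%, Fisher's exact test, adjusted p = 0.237), TAATTA (15.3% against 13.6%, exact adjusted p = 0.324) and CGATA (31.2% in both). The TATA box (10.3% against 10.9%), the DNA replication-related element (3.75% against 3.33%) and the CTCF core (1.13% against 0.654%) were not either (exact adjusted p = 0.706, 0.702 and 0.351). The 2 lower motifs, CACACACA and CAGCTG, were not past the threshold without replicate 2 or without replicate 3.

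Windows within 100 bp of summits at start sites differed in 4 motifs from windows at the same offset from start sites without a peak. Many of these windows do not reach the start site itself, as the median summit lay at -109 bp. Ohler motif 7 was at 14.9% of 1682 start sites with a peak against 9.87% of as many without (Fisher's exact test, adjusted p = 2.41e-04), and the GAGA repeat at 7.02% against 3.75% (adjusted p = 3.75e-04). The Su(Hw) core was at 1.13% against 0.297% (exact adjusted p = 0.0369), and the initiator consensus was lower, 19.2% against 24.2% (exact adjusted p = 0.0039). Each of these calls was lost with at least 1 replicate left out: GAGA without replicate 1 (exact adjusted p = 0.948), Ohler motif 7 and the initiator without replicate 2 (0.0508 and 0.0588) and without replicate 3 (exact adjusted p = 0.0518 for both), and Su(Hw) without any 1 of the 3 (0.423, 0.996 and 0.315). Those peak sets were smaller and start sites without a peak were drawn anew for each, so a lost call need not be a lost difference. With ribosomal protein genes left out and start sites without a peak drawn anew, the initiator (19.7% against 21.5%, exact adjusted p = 0.503) and the Su(Hw) core (exact adjusted p = 0.0720) were not past the threshold. Ohler motif 7 (exact adjusted p = 1.83e-04) and the GAGA repeat (exact adjusted p = 0.0032) were, and the homeodomain site TAATTA came past it (15.7% against 12.1%, exact adjusted p = 0.0241).

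The search over all short sequences returned composition first. All 10 top 6-mers consisted of A and T alone, and all passed the test on the other peaks, led by AAATAT, present at 31.2% of summits against 16.1% of flanks (exact McNemar test, adjusted p = 1.13e-31). Of the 10 top 8-mers, 9 passed, among them TATTTTAA (4.35% against 1.70%, exact adjusted p = 2.15e-06) and CCGGAAAC (0.621% against 0.263%, exact adjusted p = 0.0106). These 8-mers depended on which peaks ranked them: with the ranking and the test peaks exchanged, or with a window of 100 bp, 0 of the 10 top 8-mers were the same, against 7 and 6 of the 10 top 6-mers. Against windows of equal A+T content within 2000 bp, chosen after the data were seen, 0 of the top 6-mers and 1 of the top 8-mers were the same, and the 6-mers past the threshold included ACAGTG (6.83% against 4.20%, exact adjusted p = 8.24e-04) and ACACTG (5.92% against 3.68%, exact adjusted p = 0.0029), and CCGGAAAC was at 0.621% against 0.0956% (exact adjusted p = 0.0092).

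The tagged gene itself carried no IDR peak. CG12219 lies on X at 6299054 to 6301285, on the minus strand, with CG3815 and CG3823 as its nearest protein-coding neighbours. No call of the IDR list, the pooled list or the lists of replicates 1 and 3 lay within 1 kb of it, and replicate 2 had 1 such call, at rank 10226. The nearest IDR summit lay 7725 bp away. Within 50 kb there were 9 IDR peaks, against a median of 4 around 1000 random protein-coding genes, 9.6% of which had as many.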

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

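Both results below were singled out because calls appeared in lists that the comparisons of IDR peaks did not use, and no biological explanation was tested for either. Of the 2506 summits among the top calls of all 3 replicates, 7 had no IDR summit within 250 bp. Of the 18 cytosolic ribosomal protein genes without an IDR peak at their start site, 11 had a call there in the pooled list at a rank that the IDR step did not keep. Such calls were common, since 44.8% of all protein-coding genes had a pooled call of any rank at their start site, and the difference between the shares was not tested.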

How the results depend on the processing

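The alternatives with random positions or windows of equal A+T content, merged peaks and a second draw of start sites were chosen after the data were seen, and the cause of a change was not tested unless stated. Among the main results, 153 of their values under alternatives kept their direction and side of the threshold, or moved by less than the spread, while 23 counts or shares moved further, 12 differences were no longer past the threshold, 1 came past it and 1 reversed. The ribosomal protein excess did so under every alternative run (57.2 to 68.4 points), as did the share at a TSS (in points over random positions) and the excess of high-signal peaks at a TSS. By construction the peak number fell to 2093 for the higher-signal peaks and to 2506 for top calls of all 3 replicates. Replicate overlap was 68.0 to 74.4% with 1 replicate left out, 65.7% within 100 bp and 77.9% for the top 1000 calls. Arms past the threshold against TSS positions numbered 3 instead of 5 for both smaller peak sets, and 3 to 4 with 1 replicate left out. The intronic share lay -3.916 points from that of random positions of equal A+T, past the threshold. Of the 8-mers, 3 of 10 passed against A+T-matched windows.

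With each peak given to its nearest gene at any distance, 7 lists instead of 2 lay above other genes, and insulator protein genes, 8.82 points above, were no longer past the threshold. Within genes of equal TSS class the tRNA difference shrank to -3.43 points and the small nucleolar RNA difference to -2.73 points, and both were no longer past it. The small nucleolar RNA difference was -2.78 points for the higher-signal peaks, -3.04 points for top calls of all 3 replicates and -4.14 to -3.53 points with 1 replicate left out, lost without replicate 1 and without replicate 2. It reversed to 1.66 points with a TSS window of 1000 bp. The cytochrome P450 difference was no longer past the threshold at -6.67 points for the higher-signal peaks, -5.41 points for top calls of all 3 replicates and -7.27 points with a window of 200 bp. It was -8.52 to -6.69 points with 1 replicate left out, lost without replicate 2 and without replicate 3.

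Motifs below their flanks numbered 0 to 3 with 1 replicate left out, 1 for top calls of all 3 replicates, 0 with a window of 200 bp and 0 with flanks 1000 bp away. CAGCTG ran from -2.02 to 0.101 points with 1 replicate left out, reversed without replicate 2, and reversed to 2.05 points with a window of 200 bp. The CA repeat reversed to 0.0955 points with flanks 1000 bp away. Against start sites without a peak, the motifs above numbered 1 to 3 with 1 replicate left out, 0 for the higher-signal peaks, 1 with a window of 50 bp and 9 with one of 200 bp. The motifs below numbered 0 to 1 with 1 replicate left out, 0 for the higher-signal peaks and 0 with a window of 50 bp. Among single motifs and arms, 128 values kept direction and side, 50 were no longer past the threshold and 3 reversed. Depth limits cannot be given, as no read counts were used.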

Other observations

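The comparison of distal peaks and the test of summit position in the first 2 paragraphs were chosen after the data were seen, as were the tests of core promoters, of composition in any call and of composition between replicates. Of 31 lists of genes, 5 were nearest to peaks away from start sites more often than to random positions of the same chromosome and annotation class, and 1 less often. The 2374 summits over 500 bp from any TSS were given to the gene of the nearest TSS. Genes of the Polycomb and trithorax group received 11 such peaks against 2.32 ± 1.5 (SD over 1000 placements) at random (permutation, adjusted p = 0.0155), the highest at trx in an intron (3R, 14283727 to 14284035, rank 82). Insulator protein genes received 10 against 2.92 ± 1.66 (permutation, adjusted p = 0.0155), led by an intronic peak of Trl (3L, 14759325 to 14759714, rank 25). Segment polarity and signalling genes received 29 against 10.3 ± 3.16 (permutation, adjusted p = 0.0155), the highest upstream of ptc, the Hedgehog receptor gene (2R, 8644271 to 8644517, rank 450). Muscle and mesoderm genes received 24 against 11.7 ± 3.44 (permutation, adjusted p = 0.0413), led by kirre (rank 311), and heat shock and chaperone genes 6 against 0.983 ± 0.959 (adjusted p = 0.0248), led by Hsp83 (rank 326). Chemoreceptor genes received 9 against 21.6 ± 4.46 (permutation, adjusted p = 0.0155). The other lists were not past the threshold, among them Hox (adjusted p of 0.914), gap (0.186), pair-rule (0.380), dorsoventral (0.0774), neural fate (1), ecdysone pathway (0.103) and Hippo pathway genes (0.0531). Cytosolic ribosomal protein genes received 0 distal peaks against 2.96 ± 1.70 (permutation, adjusted p = 0.272). The random positions were not matched on distance to a TSS. Each peak was placed independently, although several can lie at 1 gene, as at Trl (ranks 25 and 831). With each peak given to its nearest gene at any distance, 6 of the 23 insulator protein genes carried one. The test thus counts peaks and not genes.

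Summits at ribosomal protein genes sat closer to the start site than other promoter summits. Their median position was -2 bp (64 summits) and that of the other 1749 promoter summits -116 bp, a difference of 114 bp (permutation test, 100000 permutations, two-sided, p = 1e-05, the smallest they can give).

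The high share of ribosomal protein genes with a peak could come from recovery of abundantly transcribed genes in general, from more start sites per gene or from the TCT initiator at their promoters. Of 43 other abundant housekeeping genes, a list written when Gapdh2 was already known to hold a strong peak, 46.5% carried a peak (interval 31.2 to 62.3%, 45.2% without Gapdh2). That is above other genes (Fisher's exact test, p = 4.03e-07) and below ribosomal protein genes (p = 3.11e-04). No expression values were used, so the lists may differ in abundance, and this comparison leaves abundance open as a cause. Within genes of equal TSS class the odds ratio was 19.02, which argues against the number of start sites. Outside ribosomal protein genes, windows around summits at start sites held the TCT consensus 0.989 points more often than windows without a peak (Fisher's exact test, adjusted p = 0.759). These windows reach 100 bp from the summit, and the median summit outside ribosomal protein genes lay at -116 bp. Many windows thus miss the start site, so the test cannot decide on the initiator, which stays open. No mock immunoprecipitation was used here to measure recovery of open promoters without the tag.

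The A+T rise at summits might reflect core promoters or a composition bias shared by all calls. Summits over 500 bp from a TSS rose by 7.55 points (interval 7.10 to 8.004), which argues against promoter position as the cause. The lowest-ranked calls of replicates 1, 2 and 3 lay -2.17, 0.0362 and -1.51 points from their flanks, at most 0.00384 times the rise of the same replicate's top calls. A rise of every call alike was thus not seen. Calls were ranked by signal, however, and a bias toward A+T that raises signal would itself place A+T-rich calls at the top. The values cannot decide on such a bias. A bias of the libraries toward A+T stays open. The rise also differed between replicates and was 7.02 points over the top calls shared by all 3. No biological explanation was tested, as the design has 1 group.

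Replicate 1 shared fewer of its top calls than replicates 2 and 3 shared with each other, and the base composition of the top calls is a candidate explanation. Calls were drawn to the same A+T distribution in every replicate, 4186 per replicate. The lead of the pair of replicates 2 and 3 over the higher pair with replicate 1 went from 4.04 points (95% bootstrap interval 2.83 to 5.22) to 2.10 points (0.991 to 3.07). The drawn calls cannot all be among the top 4187, since mean A+T in replicate 1 went from 61.0% to 63.7%. The change in the lead thus also involves other calls. Part of the lead remained at equal composition, and how much of it composition accounts for stays open. A wider scatter of summits in replicate 1 would have brought its pairs level at 500 bp. There its highest value was 71.5%, below the 74.8% of the lower direction of replicates 2 and 3. The labels name no batch, and a difference between the embryo collections was not tested.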
